A study of Rattus norvegicus with 6 samples.

How the data were processed

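RNA sequencing of neonatal rat ventricular myocytes was analysed in 6 libraries, 2 for each of 3 groups (phenylephrine with a control hairpin; phenylephrine, TSA and the control hairpin; phenylephrine, TSA and a JIP1 hairpin), treated for 3 days per the labels' protocols. RNA was extracted with a column kit and libraries were made with an Illumina kit, per the labels' protocols. The authors deposited 1 table of FPKM values per gene, with 13843 rows and a column per library. Its header gives no unit. Cufflinks, which reports FPKM, and the genome build rn6 are named per the submitters' processing notes, with no version and no role, and the size of the values and their whole-read steps are those of FPKM. The aligner, the annotation, any read filter and the kit's strand are not given in the sources used here, so reads shared between paralogs or between overlapping genes on opposite strands cannot be told apart. The labels write of a JIP1 knockout in the title and of a short hairpin in the treatment, and the hairpin wording is used here.

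The table holds 13556 distinct symbols, of which 250 stand on several rows (537 rows). Each row was kept as its own feature, and such rows are named by their place, as in listing 1 of 2. Of the symbols, 12356 matched a current symbol and 13315 a current or older one in a RefSeq gene table of the assembly GRCr8. That build differs from the one the values were made on, so it was used only to check names, and no coordinates are given. Values between 0 and 0.001 FPKM occurred 226 times and were used as deposited.

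FPKM keeps no totals, but where reads are counted whole the low values of a gene are multiples of what 1 read is worth in each library. Features below 0.3 FPKM in both libraries of a pair were used, with this limit raised in proportion for libraries shallower than the first. Of these, 52.6% to 84% had ratios within 0.01 (log2) of a ratio of small whole numbers, against 2.3% to 13.1% at shifted ratios. The depth of each library relative to the first came from its most frequent ratio of low values. A far shallower library had a separate rule. Since any ratio of small whole numbers counted, these shares alone do not fix the depth. The method was tested only on data simulated at relative depths close to those reported below, with 1 library far shallower. How well it does at other depths was therefore not checked. The ratio that set the depth of the shallowest library was held by 26 features. Counting intervals were not computed, since absolute depth is unknown.

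All tests used log2(FPKM + 1) of the features with a mean of at least 1 FPKM over the 6 libraries (10359 of 13843). A linear model with 1 mean per group was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, with a prior variance that follows the mean level (3 residual and 3.27 prior degrees of freedom), and the 3 comparisons were taken from it. P-values are two-sided and adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Using all groups lets each comparison borrow the spread of the group it does not compare. No scaling beyond that of the authors was applied. On data simulated with the fitted spread of these 10359 features and 200 changed ones (20 draws), a change of 1 on the log2 scale was found in 7.7% of features for the TSA comparison and 6.1% for the JIP1 hairpin comparison, a change of 2 in 64.5% and 61.6%, a change of 3 in 89.7% and 87.1%, and a change of 4 in 95.9% and 96.1%. The share of false calls was 6.25% and 5.43% in these simulations. Their noise was independent between genes and alike in all libraries, unlike these data, so the shares may not hold for the real calls.

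Before the data were examined, 26 gene lists were written for heart muscle, JIP1 biology, TSA and the other cell types that such cultures can hold. Lists with at least 5 features tested were analysed (24); erythroid markers (1 feature) and Schwann cell and neural crest markers (3) had too few. Each list was tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma. With the preset correlation 12, 6 and 11 lists passed in the 3 comparisons (TSA, JIP1 hairpin, both against PE), and with an estimated correlation 0, 0 and 0. The fry test for a shift in one direction passed for 3, 0 and 1 lists (neuronal, stress and smooth muscle with TSA, neuronal with both), and its test for change in either direction for 15, 15 and 21. Neither fry test compares a list with other genes. Several genes belong to more than one list. Where genes of a list are counted, each tested feature counts, so a symbol with several listings can count more than once.

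Genes were named by a rule fixed at the same time as the lists: Mapk8ip1; among called features with a symbol, non-overlapping groups and a mean of at least 5 FPKM in the higher group, the 8 largest rises and 8 largest falls; for each list that passed camera, the 4 members with the smallest p; Nppa, Nppb, Acta1, Myh6, Myh7 and Atp2a2; and up to 6 features called for both TSA and the hairpin in each relation of signs. Named outside the rule, after their values were seen, were Kif5c, Mapt and Notch3 with TSA, and Hspb1 and Cryab with the JIP1 hairpin. So were the features that illustrate zeros, low values and very large values (Rpl32, Ppia, Gapdh, Actb, Amph and Evc). The genes of the closing section that the report does not name were also outside the rule. A gene that the rule reached is not reported here. The relation of comparisons that share libraries was set against 100 simulations of unchanged groups with the same shared libraries.

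The alternatives were a pseudocount of 0.1, no filter and a filter of 5 FPKM, trimmed-mean scaling, quantile normalization, the replicate number as a block, a fit of only the 2 groups compared, no trend of the prior variance, and leaving out each of the 6 libraries. Weighting of libraries, and leaving out symbols with several listings and small RNA genes, were added after seeing the data. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.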

Results

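RNA from cultures of neonatal rat ventricular myocytes (NRVM), the muscle cells of the newborn rat heart, was measured by RNA sequencing in 6 libraries that fall into 3 groups of 2. Every culture received phenylephrine (PE), an alpha-1 adrenergic agonist that is widely used to make cultured cardiomyocytes grow. The first group received PE and a control short hairpin RNA (PE), the second PE, TSA and the control hairpin (PE+TSA), and the third PE, TSA and a hairpin against JIP1 (PE+TSA+shJIP1), each for 3 days. TSA is the usual abbreviation of trichostatin A, an inhibitor of histone deacetylases, although the labels do not spell it out. JIP1, encoded by Mapk8ip1, is a scaffold protein of the JNK kinase cascade that also binds the motor protein kinesin. The design gives 3 comparisons: the effect of TSA in the presence of PE, the effect of the JIP1 hairpin in the presence of PE and TSA, and both together against PE. Untreated cultures, and the hairpin without TSA, were not analysed here. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

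The table listed 13843 features in FPKM, a read density scaled to transcript length and library size. Its low values lie at whole-read steps and gave the relative depth of the libraries, although not their totals. Against PE replicate 1, PE replicate 2 had 0.048 of the depth (20.8 times shallower), PE+TSA replicates 1 and 2 had 1.34 and 0.854, and PE+TSA+shJIP1 replicates 1 and 2 had 0.903 and 0.72. PE replicate 2 listed 3667 features at 0 and the other 5 libraries 1407 to 1837, and 39 features were at 0 in that library alone while above 5 FPKM in the other 5. Exact zeros were not always absence of RNA: the housekeeping genes Rpl32 and Ppia were listed at 0 in 4 and 2 libraries. Single features took very large values in single libraries, with Amph (listing 1 of 2) at 121180 FPKM in PE+TSA replicate 2 and Evc at 211779 FPKM in PE+TSA+shJIP1 replicate 1. Over the 10359 features tested, log2 values of libraries of one group correlated across genes at 0.896 (PE), 0.898 (PE+TSA) and 0.891 (PE+TSA+shJIP1), and those of different groups at 0.776 to 0.91; genes are not independent replicates. All fold changes below are on the log2(FPKM + 1) scale, which understates the change of low genes, and all adjusted p-values are from limma with 2 libraries per group.

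Mapk8ip1, the gene the hairpin targets, was measured at 3.77 and 4.39 FPKM in the PE libraries, 14.6 and 17.9 in the PE+TSA libraries, and 1.8 and 3.65 in the PE+TSA+shJIP1 libraries. Both hairpin libraries therefore lay below every other library for this transcript, and the 2 PE+TSA libraries above every other. The log2 change was 1.76 ± 0.34 (SE) with TSA (unadjusted p = 0.00185, limma adjusted p = 0.0852) and -2.25 ± 0.34 with the hairpin in the presence of TSA (unadjusted p = 0.00049, limma adjusted p = 0.077). Neither passed the threshold over all features tested. Against PE alone, PE+TSA+shJIP1 differed by -0.49 ± 0.34 (adjusted p = 0.369).

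**Figure D1:**
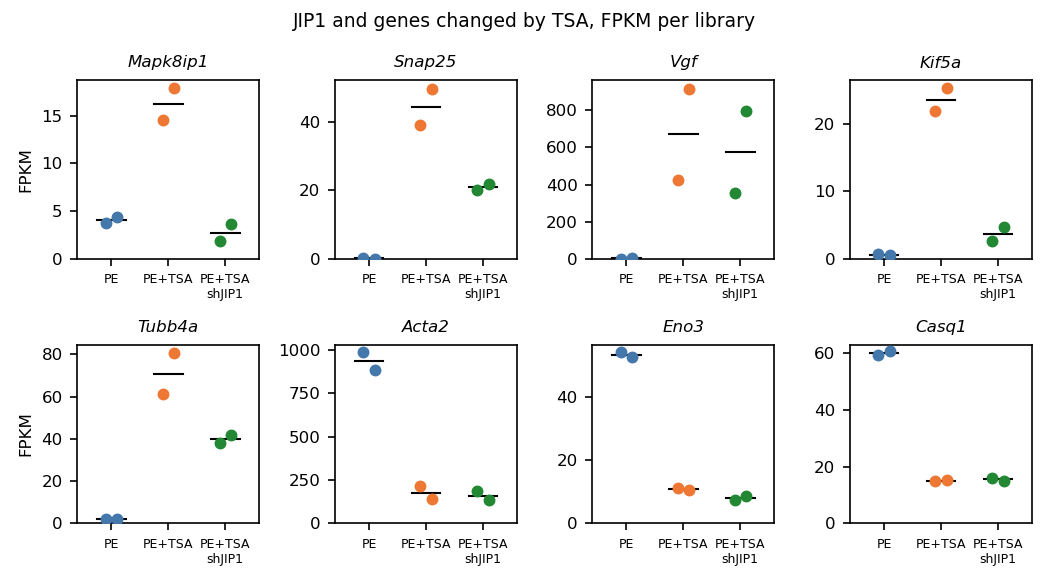
FPKM (vertical axes, linear from 0) of Mapk8ip1 and 7 genes changed by TSA in each library of the 3 groups (horizontal axes); points are the 2 libraries of a group and bars their mean. Mapk8ip1 was at 14.6 and 17.9 FPKM in PE+TSA and at or below 4.39 in the other 4 libraries, and Snap25, Vgf and Tubb4a were higher in both TSA-treated groups than in PE.

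The first comparison asks what TSA changes in PE-treated myocytes. Vgf, Snap25 and Kif5a of the neuronal list and Tubb4a of the tubulin list were among the genes that rose. Vgf, a secreted neuropeptide precursor, went from 0.0691 and 0.719 FPKM in PE to 422 and 919 in PE+TSA (log2 change 8.85 ± 0.52 SE, limma adjusted p = 0.00378). Snap25, a SNARE protein of synaptic vesicle release, was at 0.22 in PE replicate 1, listed at 0 in PE replicate 2, and at 39.3 and 49.9 in PE+TSA (adjusted p = 0.00308). Tubb4a, a beta-tubulin abundant in brain, rose from 2.14 and 1.98 to 61.1 and 80.6 FPKM (4.54 ± 0.23, adjusted p = 0.00308). Kif5a, a neuronal kinesin heavy chain, rose from 0.617 and 0.536 to 21.9 and 25.4 FPKM (3.96 ± 0.33, adjusted p = 0.0169).

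Acta2, Eno3, Xirp2, Fhl1, Casq1, Des and Hspb6 were among the genes that fell. Acta2, smooth muscle alpha-actin, fell from 988 and 886 FPKM to 213 and 139 (log2 change -2.43 ± 0.29, limma adjusted p = 0.0332). Eno3, the muscle enolase of glycolysis, fell from 54.1 and 52.6 to 11.2 and 10.5 (-2.20 ± 0.21, adjusted p = 0.0295). Xirp2, a protein of the intercalated disc, and Fhl1, a LIM-domain protein of the sarcomere, changed by -2.31 ± 0.24 and -2.13 ± 0.25 (adjusted p = 0.0307 and 0.0332). Casq1, a calcium-binding protein of the sarcoplasmic reticulum, and Des, the intermediate filament desmin, changed by -1.92 ± 0.19 and -1.86 ± 0.24 (adjusted p = 0.0307 and 0.0372). The small heat shock protein Hspb6 fell from 667 and 539 to 197 and 182 FPKM (adjusted p = 0.0386).

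In all, 84 of 10359 features passed the threshold with TSA, 65 up and 19 down, each with a change of at least 1.40 on the log2 scale and with groups that did not overlap. At an unadjusted p under 0.05 there were 1938, where chance gives 518, and the groups did not overlap for 50.6% of features, where chance gives 33.3%. Among the largest rises were also Cox6b2, a testis-type cytochrome c oxidase subunit, listed at 0 in both PE libraries and at 35.9 and 57.3 FPKM in PE+TSA (adjusted p = 0.00308), and Oxct2a, at 0 in both PE libraries and 14.5 and 21.1 in PE+TSA (adjusted p = 0.0108). Gstt3, a glutathione transferase, was at 3.03 and listed at 0 in PE and at 49.2 and 53.4 in PE+TSA (adjusted p = 0.0379). One of the 2 listings of Frg1 was at 0 in both PE libraries, 47.9 and 50.9 in PE+TSA and 0 again in both PE+TSA+shJIP1 libraries (adjusted p = 0.00321 with TSA). The largest falls included Krt10, a keratin (27.7 and 36.7 to 0.411 and 1.79 FPKM), Spink8 (346 and 788 to 40.6 and 24.9), Rilp (14.4 and 11.7 to 1.55 and 1.96), Lctl (listing 2 of 2; 72.2 and 91.2 to 9.68 and 4.25) and the chemokine Ccl4, at 10.3 and 21.5 in PE and listed at 0 in both PE+TSA libraries (adjusted p from 0.0307 to 0.0386 for these 5). The median change of all features was 0.10 as deposited, 0.04 with trimmed-mean scaling and -0.02 with quantile normalization, so the changes stand relative to a centre that moves by about that much. Without PE replicate 1 it was 250 (223 up, 27 down), and without PE replicate 2 it was 16 (9 up, 7 down). Without PE+TSA replicate 1 or 2 it was 21 (18 up, 3 down) and 14 (all up), and without either PE+TSA+shJIP1 library 6 (all up). Of these, 63, 8, 7, 4, 5 and 5 were among the 84. Vgf, Snap25, Tubb4a and Cox6b2 passed in all 16 alternative settings, and they were the only 4 of the 24 called genes named by the fixed rule to do so.

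Of 24 gene lists tested, 12 passed with TSA in limma's camera test with its preset correlation, 2 up and 10 down. Of 33 neuronal genes that the repressor REST silences outside the nervous system, 9 rose and none fell over all genes, and 19 rose adjusted over the list alone (median log2 change 1.49, camera adjusted p = 1.65e-12; adjusted p = 0.179 with an estimated correlation). Among them, Scg5, a chaperone of secretory granules, was listed at 0 in both PE libraries and at 10.5 and 13.3 FPKM in PE+TSA (adjusted p = 0.0155). Of 49 cell cycle genes none passed over all genes and 2 fell adjusted over the list alone, but 45 were lower with TSA (median -0.90, camera adjusted p = 1.29e-11; adjusted p = 0.556 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at 16.4 and 12.3 FPKM in PE and 2.04 and 2.95 in PE+TSA (adjusted p = 0.0729), and thymidine kinase Tk1 at 14.5 and 13.6 against 3.48 and 2.37 (adjusted p = 0.0731). Of 26 sarcomere genes, Des fell over all genes and 7 fell adjusted over the list alone, and 23 were lower (median -0.87, camera adjusted p = 9.05e-09; adjusted p = 0.556 with an estimated correlation). Troponin C, Tnnc1, was at 957 and 829 FPKM in PE and 255 and 94.8 in PE+TSA (adjusted p = 0.0845). In the fibroblast and extracellular matrix list of 31, Thy1, a surface marker of fibroblasts and neurons, rose from 3.29 and 1.56 to 20.9 and 24.7 FPKM (adjusted p = 0.0373), while 24 were lower and 7 fell and 1 rose adjusted over the list alone (median -0.81, camera adjusted p = 5.02e-06; adjusted p = 0.556 with an estimated correlation). Of 13 smooth muscle and pericyte markers Acta2 fell, and 7 fell and 1 (Notch3) rose adjusted over the list alone (median -0.78, camera adjusted p = 0.000132; adjusted p = 0.179 with an estimated correlation). Without PE replicate 2 the medians of the cell cycle and fibroblast lists were -1.46 and -0.31. Without PE replicate 1 that of the cell cycle list was -0.52, and without PE+TSA replicate 1 or 2 that of the sarcomere list was -1.44 or -0.49. The fibroblast list was at -0.45 without PE+TSA replicate 1. The median of the neuronal list was 3.04 with a pseudocount of 0.1 and 2.96 with a filter of 5 FPKM.

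The interferon list differed between libraries of a group. All but 2 of its 38 genes were lower with TSA and none passed, over all genes or adjusted over the list alone (median -1.43, camera adjusted p = 9.08e-08; adjusted p = 0.62 with an estimated correlation). The median log2 value of the list was 4.97 and 4.95 in PE, 4.79 and 2.32 in PE+TSA, and 4.40 and 3.71 in PE+TSA+shJIP1. The median difference of its genes between replicates 1 and 2 was 0.12, 2.46 and 0.89 in these groups, the last 2 at the 100th percentile of 10000 random lists matched for level. Without PE+TSA replicate 2 the change was -0.08 (camera adjusted p = 0.197), against -2.44 without PE+TSA replicate 1. Oas1a, an antiviral oligoadenylate synthetase, was at 15.3 and 20.9 FPKM in PE and at 6.61 and 0 in PE+TSA (adjusted p = 0.193).

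Among the other lists that passed with TSA, 1 of 34 endoplasmic reticulum stress and heat shock genes fell, Hspb6, and 5 fell adjusted over the list alone (camera adjusted p = 3.54e-06; adjusted p = 0.179 with an estimated correlation). In the hypertrophy list of 30, Fhl1, Xirp2 and Enah fell and the deubiquitinase Uchl1 rose from 51.4 and 48.9 to 167 and 164 FPKM; 10 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.467 with an estimated correlation). The glycolysis list of 22 passed with Eno3 as its only member past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.556 with an estimated correlation). The calcium handling and ion channel list of 41 passed with Casq1, and adjusted over the list alone 3 fell and 1 rose (camera adjusted p = 0.0412; adjusted p = 0.716 with an estimated correlation). None of the 57 oxidative phosphorylation genes or 47 autophagy and lysosome genes passed, over all genes or adjusted over the list alone, although the lists passed downward and upward (camera adjusted p = 0.0122 and 0.0383; adjusted p = 0.839 and 0.556 with an estimated correlation). Without PE+TSA replicate 2 the calcium, autophagy and oxidative phosphorylation lists no longer passed (median 0.06, 0.23 and -0.004 on the log2 scale). Without PE replicate 1 the glycolysis, autophagy and oxidative phosphorylation lists did not (-0.12, 0.37 and 0.105). Without PE replicate 2 the calcium list did not pass (-0.16), and with quantile normalization the calcium and oxidative phosphorylation lists did not. The calcium list also missed the threshold with a filter of 5 FPKM (camera adjusted p = 0.0511). The calcium and autophagy lists did so without symbols with several listings and small RNAs (0.0516 for both). The median of the calcium list, -0.217 as reported, was -0.085 with no filter, -0.117 without PE replicate 1 and -0.473 without PE+TSA replicate 1. That of the oxidative phosphorylation list, -0.16, was -0.345 without PE replicate 2 and -0.306 without PE+TSA replicate 1. The hypertrophy list was at -0.53 without PE+TSA replicate 2 and -0.215 with a filter of 5 FPKM, against -0.33. Of the lists that did not pass, 2 of 26 kinesin and dynein transport genes rose, Kif5a and Kif5c (camera adjusted p = 0.119), and 2 of 20 tubulin and microtubule genes rose, Tubb4a and Mapt (0.474). The class I, II and IV histone deacetylases (0.073), histone deacetylase inhibitor responsive genes (0.477), JNK pathway (0.747), apoptosis and p53 (0.834), ribosomal proteins (0.547), fatty acid oxidation (0.547), immediate early genes (0.547) and inflammation (0.547) lists did not pass. Nor did endothelial markers (median -0.21, camera adjusted p = 0.547) and macrophage markers (median -0.28, camera adjusted p = 0.278). Of 23 histone deacetylase inhibitor responsive genes, 4 rose and 1 fell adjusted over the list alone. For the endothelial, fatty acid oxidation, immediate early and inflammation lists the median, the mean and the direction of the test did not all have one sign.

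The genes classically followed in hypertrophy did not pass with TSA over all genes, although Nppa and Myh7 fell adjusted over the list alone (adjusted p = 0.0274 for both). The natriuretic peptide gene Nppa was at 3760 and 3247 FPKM in PE and 1748 and 1428 in PE+TSA (log2 change -1.14 ± 0.31, limma adjusted p = 0.147). The slow myosin heavy chain Myh7 was at 488 and 498 against 149 and 37.3 (adjusted p = 0.149), and the fast one, Myh6, at 271 and 163 against 172 and 31.7 (adjusted p = 0.388). Nppb was at 1130 and 882 against 1000 and 1052 (adjusted p = 0.95), skeletal actin Acta1 at 2043 and 1881 against 2821 and 3069 (adjusted p = 0.314), and the calcium pump gene Atp2a2 at 337 and 260 against 251 and 178 (adjusted p = 0.388).

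**Figure D2:**
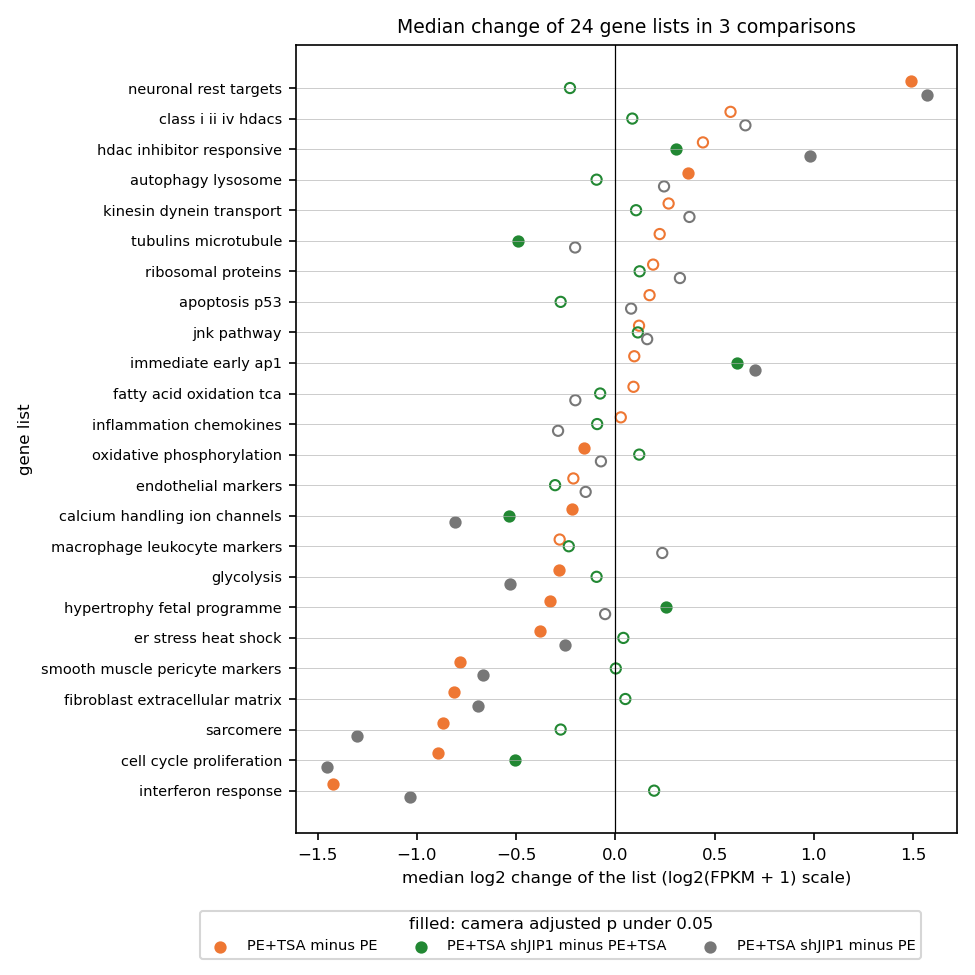
Median log2 change (horizontal axis, log2(FPKM + 1) scale) of the 24 gene lists tested (vertical axis) in the 3 comparisons; each point is a list in a comparison, filled where the camera adjusted p with the preset correlation was under 0.05. The neuronal list had a median of 1.49 with TSA and 1.57 with TSA and the JIP1 hairpin, and the cell cycle list -0.90 and -1.46; none passed with an estimated correlation.

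The second comparison asks what the JIP1 hairpin changes in cells that also receive PE and TSA. Atf3, Ctgf, Fhl1, Flnc, Xirp2 and Ccnd2 were among the genes that rose with it. Atf3, a stress-induced transcription factor, rose from 2.01 and 1.99 FPKM to 27.4 and 36.3 (log2 change 3.44 ± 0.30, limma adjusted p = 0.0241), and Ctgf, a secreted matricellular protein, from 110 and 186 to 1235 and 1612 (3.29 ± 0.32, adjusted p = 0.027). Fhl1 rose from 178 and 141 to 1315 and 1248 FPKM (3.01 ± 0.25), Flnc, the filamin of muscle, from 37.1 and 26.6 to 222 and 232 (2.81 ± 0.22) and Xirp2 from 16.5 and 12.5 to 99.8 and 114 (2.81 ± 0.24; adjusted p = 0.0241 for these 3). Cyclin D2, Ccnd2, rose from 34.5 and 24.9 to 311 and 214 FPKM (3.10 ± 0.27, adjusted p = 0.0241).

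Among the genes that fell, Snurf was at 55.6 and 41.8 FPKM in PE+TSA and at 7.61 and 5.5 with the hairpin (log2 change -2.72 ± 0.25, limma adjusted p = 0.0252). Hmga1, a chromatin protein that bends DNA, fell from 151 and 164 to 36.3 and 39.7 (-2.02 ± 0.18, adjusted p = 0.0241). The phosphatase gene Ptp4a3 (19.4 and 21.9 to 4.15 and 2.63 FPKM), the transcription factor Nfic (78.2 and 76.3 to 18.3 and 23.3), the small ubiquitin-like modifier Sumo3 (51.6 and 50.9 to 12.5 and 15.1), Tmem51 (23.4 and 20.6 to 4.9 and 5.78) and Aes, a Groucho-family corepressor (387 and 325 to 110 and 97.2), also fell (adjusted p from 0.0375 to 0.0488). Some of the most extreme features were single listings of symbols with several. Akap7 (listing 3 of 3) was at 0 in all 4 libraries without the hairpin and at 129 and 497 FPKM with it (adjusted p = 0.0241), and Cmss1 rose in listings 1 and 2 of 3 (3.45 ± 0.36 and 4.46 ± 0.29, adjusted p = 0.0339 and 0.0155). The listing of Frg1 that appeared with TSA was at 0 in both hairpin libraries (adjusted p = 0.0128).

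**Figure D3:**
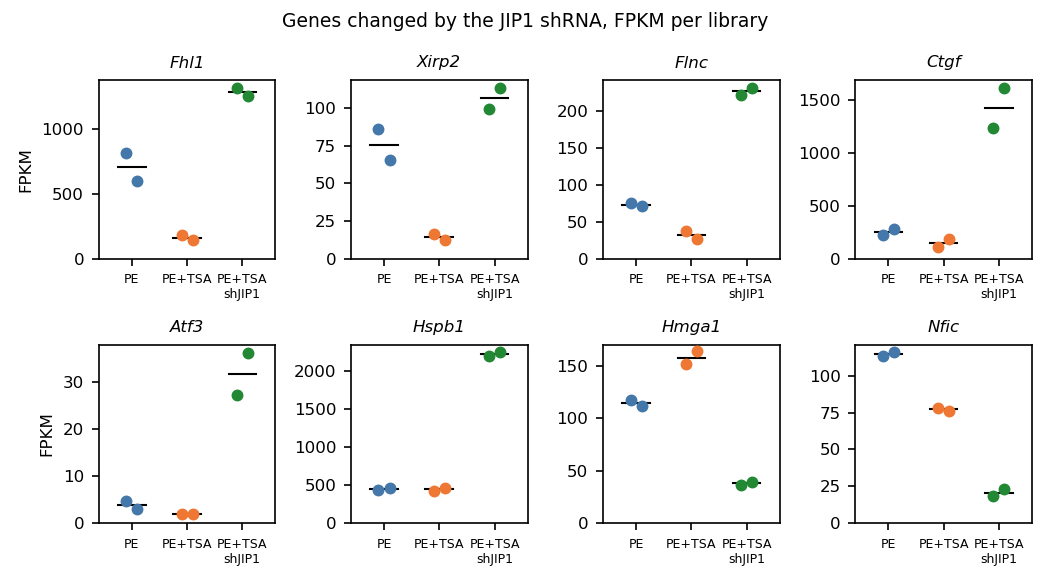
FPKM (vertical axes, linear from 0) of 8 genes changed by the JIP1 hairpin in each library of the 3 groups (horizontal axes); points are the 2 libraries of a group and bars their mean. Fhl1 and Xirp2 were lower in PE+TSA (178 and 141, 16.5 and 12.5 FPKM) than in both other groups, and Hspb1 was at 2192 and 2248 FPKM with the hairpin against 429 to 459 in the other 4 libraries.

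The hairpin moved 30 of 10359 features past the threshold, 19 up and 11 down, each by at least 1.61 on the log2 scale. At an unadjusted p under 0.05 there were 1540, where chance gives 518, and the groups did not overlap for 50% of features, where chance gives 33.3%. The median change of all features was -0.003. The calls and their balance depended on single libraries. Without PE+TSA replicate 1 there were 2 rises and 13 falls, and without replicate 2 no rise and 9 falls, with 2 and 0 of these among the 30. Without PE replicate 1 or 2 there were 5 rises and 5 falls, and 3 rises and 5 falls (5 and 3 among the 30). Without PE+TSA+shJIP1 replicate 1 or 2 there were 11 rises and 3 falls, and 15 rises and 4 falls (2 and 3 among the 30). None of the 20 called genes named by the fixed rule passed in every alternative, whereas all kept their direction.

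Of the 24 lists, 6 passed with the hairpin, 3 up and 3 down, and none with an estimated correlation. In the immediate early and AP-1 list of 37, Atf3 and Cyr61 (listing 2 of 2) rose over all genes, Cyr61 from 103 and 77.7 to 425 and 575 FPKM, and 7 rose and 1 fell adjusted over the list alone (median 0.61, camera adjusted p = 7.7e-05; adjusted p = 0.825 with an estimated correlation). In the hypertrophy list, Fhl1, Xirp2, Flnc and Ctgf rose, and 10 rose and 2 fell adjusted over the list alone (median 0.255, camera adjusted p = 0.00146; adjusted p = 0.825 with an estimated correlation). In the list of 23 genes responsive to histone deacetylase inhibitors, Ctgf, Gadd45g, a DNA-damage-inducible gene, and the histone gene Hist3h2a rose. Hist3h2a went from 32.5 and 27.6 to 113 FPKM in both hairpin libraries. Adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.0119, and 0.825 with an estimated correlation). With TSA, Ctgf, Gadd45g and Hist3h2a had not risen (log2 change -0.809, -0.688 and -0.211, none past the threshold). Their rise with the hairpin therefore does not add to a rise with TSA. None of the 41 calcium handling and ion channel genes passed over all genes, 7 fell adjusted over the list alone, and 34 were lower (median -0.53, camera adjusted p = 7.7e-05; adjusted p = 0.825 with an estimated correlation). The potassium channel gene Kcnk3 was at 33.8 and 28.7 FPKM without the hairpin and 10.3 and 11.8 with it (adjusted p = 0.0845). Of 20 tubulin and microtubule genes, 19 were lower and none passed, over all genes or adjusted over the list alone (median -0.49, camera adjusted p = 0.000238; adjusted p = 0.825 with an estimated correlation). In this list Mapt, the microtubule-associated protein tau, was at 37.1 and 49.8 FPKM without the hairpin and 21.1 and 17.5 with it (adjusted p = 0.152). In the cell cycle list Ccnd2 rose, and adjusted over the list alone 1 rose and 1 fell, while 39 of 49 were lower (median -0.51, camera adjusted p = 0.0299; adjusted p = 0.957 with an estimated correlation). The cell cycle list no longer passed without PE+TSA replicate 1 (median -0.25) or PE+TSA+shJIP1 replicate 2 (-0.41), nor with a filter of 5 FPKM (-0.42), and was at -0.79 without PE+TSA replicate 2. Without PE+TSA+shJIP1 replicate 2 the calcium and immediate early lists were at -0.235 and 0.315, and the list of histone deacetylase inhibitor responsive genes no longer passed (0.26). Without PE+TSA+shJIP1 replicate 1 the calcium, immediate early, hypertrophy and inhibitor-responsive lists were at -0.84, 0.98, 0.39 and 0.68. Without PE+TSA replicate 1 the calcium and hypertrophy lists were at -0.31 and 0.49. With quantile normalization the hypertrophy and inhibitor-responsive lists did not pass (medians 0.146 and 0.297, camera adjusted p = 0.0601 for both).

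The other 18 lists had camera adjusted p-values from 0.239 to 0.992 with the hairpin. In the stress list of 34, the small heat shock genes Hspb1 and Cryab rose, Hspb1 from 429 and 458 to 2192 and 2248 FPKM (limma adjusted p = 0.0241) and Cryab from 1225 and 1198 to 7174 and 7675 (adjusted p = 0.0403), and 3 rose adjusted over the list alone. Markers of fibroblasts (median 0.05), smooth muscle (0.002), endothelium (-0.30) and macrophages (-0.235) did not pass. The sarcomere list was at -0.28 (camera adjusted p = 0.388) and the JNK pathway list at 0.11 (0.239). For the histone deacetylase, fibroblast and macrophage lists the median, the mean and the direction of the test did not all have one sign.

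With the hairpin, Nppb was at 2277 and 1816 FPKM against 1000 and 1052 without it (log2 change 0.99 ± 0.26, limma adjusted p = 0.18, and 0.0265 adjusted over the list alone), and Acta1 at 4664 and 4703 against 2821 and 3069 (adjusted p = 0.325). Nppa (1916 and 1313 FPKM), Myh6 (117 and 41.2), Myh7 (152 and 48) and Atp2a2 (236 and 181) did not differ from PE+TSA by more than the spread between libraries (adjusted p = 0.997, 0.975, 0.931 and 0.972).

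The third comparison sets PE+TSA+shJIP1 against PE. Vgf and Snap25 were again among the largest rises. Vgf was at 355 and 795 FPKM (log2 change 8.62 ± 0.52, limma adjusted p = 0.00464), Snap25 at 20.1 and 21.8 (adjusted p = 0.00464) and Tmem59l, listed at 0 in both PE libraries, at 14 and 19.7 (adjusted p = 0.0115). Members of the cell cycle and sarcomere lists fell, among them Prc1, a protein of the mitotic spindle midzone, from 56.4 and 23.3 to 2.55 and 3.78 FPKM (-3.18 ± 0.45, adjusted p = 0.0194), and the light chain gene Myl3 from 1868 and 1330 to 391 and 350 (-2.09 ± 0.31, adjusted p = 0.0203). Acta1 rose (1.26 ± 0.27, adjusted p = 0.0442), with a range of 0.748 to 1.316 over the alternatives. Of the 54 called genes named by the fixed rule in this comparison, only 3 passed in every alternative setting: Vgf, Snap25 and Cox6b2.

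The other largest rises were Akap7 (listing 3 of 3), Cox6b2, at 43.1 and 50.6 FPKM, Gstt3, at 46.5 and 53.4, Fbxo2, a brain-enriched ubiquitin ligase subunit, at 0.386 and 0 in PE and 15.6 and 29.3 here, and Lipe (listing 2 of 2), at 3.5 and 0 in PE and 80 and 90.5 here. The largest falls were Wfdc1 (27.8 and 66.8 to 0.894 and 2.36 FPKM), Krt10, Trim72, a protein of muscle membrane repair (49.9 and 39.6 to 3.78 and 1.26), Tgfb1i1, a focal adhesion protein (153 and 142 to 11.6 and 9.86), Kitlg, the ligand of the receptor Kit (42.5 and 42.8 to 2.06 and 3.46), Pole4 (77.5 and 130 to 19.3 and 3.19), Ccl4, at 0 in both libraries here, and the small RNA gene Mir6334, at 49.5 and 1029 in PE and 0 here. The adjusted p of these 13 features ran from 0.00464 to 0.0401. In all, 857 of 10359 features passed, 426 up and 431 down (3185 at an unadjusted p under 0.05, where chance gives 518), and the groups did not overlap for 60.6%. The count was 279 and 138 without PE+TSA replicate 1 or 2, which bear on it through the shared estimate of spread and through the filter (10362 and 10291 features tested). Without PE+TSA+shJIP1 replicate 1 there were 17 rises and 1 fall (7 among the 857), and without replicate 2 there were 22 rises and 3 falls (9 among them). Without PE replicate 2 there were 11 rises and 13 falls (15 among them), and without PE replicate 1 there were 723 rises and 261 falls (513 among them).

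Of the 24 lists 11 passed, 3 up and 8 down, and none with an estimated correlation (adjusted p = 0.713 with an estimated correlation for each of the 11). Of the 33 neuronal genes 13 rose, and 23 rose adjusted over the list alone (median 1.57, camera adjusted p = 1.71e-07). Of 49 cell cycle genes 8 fell and Ccnd2 rose, and 26 fell and 1 rose adjusted over the list alone (median -1.46, camera adjusted p = 6.37e-11). Of 26 sarcomere genes 6 fell, including Myl3, Myl4 and the troponin gene Tnni3, and 8 fell adjusted over the list alone (median -1.30, camera adjusted p = 1.71e-07). Of 41 calcium handling and ion channel genes 9 fell, including Casq1, Kcnk3 and the adrenergic receptor gene Adra1a, and adjusted over the list alone 13 fell and 1 rose (median -0.81, camera adjusted p = 9.89e-07). Of 31 fibroblast and matrix genes 8 fell, including elastin, Eln, and vimentin, Vim, and Thy1 rose, with 9 falls and 2 rises adjusted over the list alone (median -0.69, camera adjusted p = 0.000456). Gbp5 was the 1 of 38 interferon genes to fall over all genes, and none did adjusted over the list alone (median -1.04, camera adjusted p = 0.000285). Among 13 smooth muscle and pericyte markers 3 fell, Acta2, Cspg4 and Myh11, and 3 adjusted over the list alone (camera adjusted p = 0.0153). Of 23 histone deacetylase inhibitor responsive genes 7 rose, including the linker histone gene H1f0 and Rhob, and 2 fell, with 11 rises and 2 falls adjusted over the list alone (median 0.98, camera adjusted p = 0.00922). Of 37 immediate early genes 4 rose and Klf4 fell, and 15 rose and 3 fell adjusted over the list alone (median 0.70, camera adjusted p = 0.0116). In the glycolysis list of 22, Eno3 and the glucose transporter genes Slc2a1 and Slc2a4 fell and Pkm rose, with 7 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0268). In the stress list of 34, Hspb1 and Cryab rose and 4 genes fell, including Hyou1 and Pdia4 of the endoplasmic reticulum, with 3 rises and 5 falls adjusted over the list alone (camera adjusted p = 0.0293).

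Leaving out 1 library moved several of these medians. Without PE replicate 2 the fibroblast and smooth muscle lists no longer passed (-0.40 and -0.66). Without PE replicate 1 the immediate early, glycolysis and stress lists did not (0.68, -0.365 and -0.23), while the fibroblast and cell cycle lists were at -1.06 and -0.96. Without PE+TSA+shJIP1 replicate 2 the immediate early and stress lists no longer passed (0.55 and -0.23), and the sarcomere, interferon and inhibitor-responsive lists were at -0.74, -0.61 and 0.62. Without PE+TSA+shJIP1 replicate 1 the immediate early and inhibitor-responsive lists were at 1.07 and 1.67. The immediate early list did not pass without symbols with several listings and small RNAs (camera adjusted p = 0.0787) nor the stress list with a filter of 5 FPKM (0.0643). The neuronal median was 3.17 with a pseudocount of 0.1 and 0.864 with no filter. Nppa, Nppb, Myh7, Myh6 and Atp2a2 had adjusted p = 0.0701, 0.0636, 0.0832, 0.255 and 0.252 against PE. Adjusted over the list alone, Nppa and Myh7 fell and Nppb rose (adjusted p = 0.0281, 0.0325 and 0.0254). For the apoptosis, hypertrophy, macrophage and tubulin lists the median, the mean and the direction of the test did not all have one sign.

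How the hairpin's effect relates to that of TSA was compared gene by gene. Fhl1, Xirp2 and Frg1 (listing 1 of 2) were called in both comparisons, each in the opposite direction, and no feature was called in both in the same direction. Fhl1 was at 815 and 595 FPKM in PE, 178 and 141 in PE+TSA and 1315 and 1248 with the hairpin, and Xirp2 at 86 and 65.6, 16.5 and 12.5, and 99.8 and 114. Independent lists of these sizes would share 0.104 features in opposite directions, and 100 simulations of unchanged groups with the same shared libraries gave at most 1. Those simulations held no changed genes, so they do not measure the overlap that shared libraries give among called features. Because both effects use the PE+TSA libraries, part or all of this excess may come from the shared libraries. Across genes the effects had Pearson r = -0.212 and Spearman rho = -0.084, against a simulated mean r of -0.504 from shared libraries alone, and a covariance of -0.132 against a simulated -0.193, a difference of 0.061. The direction depended on the libraries: r was -0.044 and 0.126 when each effect used a different PE+TSA library, -0.446 without PE+TSA replicate 1, and -0.134 without symbols with several listings and small RNAs.

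The effect of TSA alone and that of TSA with the hairpin, both against PE, shared 67 of the 84 features called with TSA, 54 up and 13 down, among them Vgf, Snap25 and Acta2. Independent lists would share 2.67 up and 0.791 down, and simulated unchanged groups at most 1. The simulated groups held no changed genes, so this does not measure the overlap from shared libraries among called features. The covariance of these effects across genes was 0.563 against a simulated 0.191, and r was 0.681 against 0.501. Of the 30 features called with the hairpin, 26 were called with the same sign against PE, 17 up and 9 down, including Hspb1, Atf3 and Hmga1, where independent lists would share 0.781 and 0.458. Their covariance was 0.421 against a simulated 0.187, with r = 0.571 against 0.494. Part of the excess in both may come from the shared libraries.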

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

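Weighted libraries and the omission of symbols with several listings and small RNAs were chosen after seeing the data. The weights were 0.69 for both PE libraries, 1.2 for both PE+TSA libraries and 1.21 for both PE+TSA+shJIP1 libraries. With 2 libraries per group they could not set the shallow PE replicate 2 apart from its partner. They only gave the PE group less weight than the others. With TSA, 84 features passed in the reported analysis. The count was 14 with no filter (more features tested, 13608), 7 with a fit of only the 2 groups, 36 with no trend of the prior variance, 44 with weighted libraries and 144 without symbols with several listings and small RNAs. For the JIP1 hairpin, 30 (19 up, 11 down) became 1 with no filter (a fall), 2 with no trend (1 up, 1 down) and 94 with weighted libraries (42 up, 52 down), which kept all 30 but turned the balance to falls. For both against PE, 857 became 372 with only the 2 groups. Features called with TSA and in reverse with the hairpin, 3, were 1 with no filter, 1 with no trend, 5 with quantile normalization and 5 with weighted libraries. Leaving out each library gave 6 to 250, 8 to 19 and 18 to 984 called features in the 3 comparisons, and 1 to 12 called in reverse; the group left with 1 library is then assumed to vary like the others. Beyond fewer samples and fewer or more features tested, the cause was not tested. Deviations from the group means, taken in the order of the replicate numbers, correlated between groups at 0.0735, 0.0396 and 0.122. These weak positive values do not show whether the replicate numbers pair the samples. With the replicate block, the counts were 28, 18 and 1063. Scaling moved the share of rises by under 10 percentage points, from 77.4% to 72.4% and 71.4% with TSA.

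Mapk8ip1 kept its direction in all alternatives. Its change with the hairpin passed only with weighted libraries (-2.25, adjusted p = 0.0471, range over alternatives 0.0471 to 0.305). Lists past camera numbered 29 over the 3 comparisons, 25 to 30 under the other fits of all 6 libraries, and 0 with an estimated correlation. The estimate was 0.885 for the interferon list, 0.698 for the sarcomere list and 0.591 for the cell cycle list, against the preset 0.01. For these lists the preset understates how far the genes vary together. For the stress and neuronal lists the estimate was only 0.0177 and 0.0581, so its size alone does not account for every loss. Over the 15 alternatives run on lists at the preset correlation (the fit of only the 2 groups was not), 407 list results stayed past the threshold and 28 did not. For the 98 calls of named genes, 1002 results under alternatives stayed past the threshold, 554 did not, and none changed direction.

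Among the named genes, directions turned only for those that did not pass. With TSA, the medians of the calcium and oxidative phosphorylation lists, which had passed downward, also turned when a single library was left out. Nppb with TSA (0.04) was at -0.026 with trimmed-mean scaling and -0.14 to 0.218 when each library was left out, lowest without PE replicate 2. With the hairpin, Nppa (0.005) was at -0.006 with trimmed-mean scaling, -0.429 with quantile normalization, and -0.267 to 0.278 when each library was left out, below 0 without PE+TSA replicate 2 (-0.141) and PE+TSA+shJIP1 replicate 1 (-0.267). Left-out libraries gave a range of -1.29 to 1.113 for Myh6, -0.791 to 1.174 for Myh7 and -0.28 to 0.216 for Atp2a2, with signs set by which PE+TSA or PE+TSA+shJIP1 library was omitted. The correlation of the TSA and hairpin effects across genes, -0.212, was -0.044 and 0.126 when each effect used a different PE+TSA library, and -0.446 without PE+TSA replicate 1. The shallow PE replicate 2 limits low features most. In simulated data, a change of 1 on the log2 scale was found in 7.7% of features with TSA.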

Other observations

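All tests of this part were chosen only after the results they bear on had been seen, at least in part, and the genes of the first 2 paragraphs were picked after their values were seen. Gstp1 and Atox1 were higher in both TSA-treated groups. Gstp1, a glutathione transferase, was at 130 and 92.9 FPKM in PE, 416 and 539 in PE+TSA (log2 change 2.10 ± 0.28, limma adjusted p = 0.0386) and 844 and 1102 in PE+TSA+shJIP1 (3.12 ± 0.28 against PE, adjusted p = 0.0108). Atox1, a copper chaperone, was at 17.2 and 12.1, 79.4 and 68.8 (adjusted p = 0.0324), and 129 and 91.8 FPKM (adjusted p = 0.0115). Of the kinesin-1 heavy chains, the motor that JIP1 binds, Kif5a was at 0.617 and 0.536, 21.9 and 25.4, and 2.69 and 4.7 FPKM, and Kif5c at 0.757 and 0.604, 5.25 and 7.31, and 15.2 and 17.8. With the hairpin, Kif5a was lower (-2.42 ± 0.33, adjusted p = 0.0628) and Kif5c higher (1.28 ± 0.30, adjusted p = 0.151), neither past the threshold. The ubiquitous Kif5b was at 306 and 253, 231 and 149, and 313 and 169 FPKM.

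H3f3b, Zfp36l1 and Patz1 were also among the features raised by the hairpin. The replacement histone gene H3f3b was at 177 and 167 FPKM in PE+TSA and 522 and 632 with the hairpin (log2 change 1.73 ± 0.20, limma adjusted p = 0.0448), and Zfp36l1, a protein that promotes decay of AU-rich transcripts, at 77.9 and 97.8 against 408 and 488 (2.34 ± 0.21, adjusted p = 0.0242). Patz1, a zinc-finger transcription regulator, was at 35.9 and 29.1 against 115 and 117 (adjusted p = 0.0458).

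Some features were listed at 0 in both libraries of a group and at a mean of 5 FPKM or more in another, such as Frg1 (listing 1 of 2), Akap7 (listing 3 of 3) and Cox6b2. There were 83, of which 23 (27.7%) carried a symbol with several listings, against 4.36% of the other 10276 features, a ratio of 6.36 (Fisher's exact test, two-sided, p = 1.14e-12). With Frg1, Akap7 and Cmss1, which prompted the test, left out, the share was 21 of 81 (25.9% against 4.3%; Fisher's exact test, two-sided, p = 3.31e-11). A candidate explanation for those 23 is that the abundance estimate moved reads between listings of one symbol. The excess of such symbols could have come out the other way, but whether their other listings fell in turn was not tested. Another 36 were small RNA genes, of 72 tested, for which this explanation was not tested. The remaining features, Cox6b2 among them, are not reached by it, and a change with TSA or the hairpin stays open for all 83.

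The medians of the fibroblast, smooth muscle and cell cycle lists were below 0 with TSA, although few or none of their genes passed over all genes. These lists passed camera only with the preset correlation (adjusted p = 0.556, 0.179 and 0.556 with an estimated one). A smaller share of non-myocytes, as the sole difference, would leave sarcomere genes level or higher, and the sarcomere list had a median log2 change of -0.871 (bootstrap 95% limits -1.35 to -0.634 over its 26 genes). Those limits ignore that the genes vary together between libraries, so they do not decide it. From the spread between libraries the difference of the list was -0.992 with 95% limits of -2.586 to 0.602 (t, 3 degrees of freedom), the median ranged from -1.438 to -0.49 without PE+TSA replicate 1 or 2, and the list did not pass with an estimated correlation (adjusted p = 0.556). With 2 libraries per group a smaller share of non-myocytes therefore stays open. The highest of the 6 medians of these 3 lists under trimmed-mean and quantile scaling was -0.813. This argues against a scaling difference of the kind that these methods correct. They moved the median of all features only from 0.097 to 0.041 and -0.021. Both centre the libraries on most features, so a shift common to most features could not be seen. An effect of TSA within the cells stays open too.

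The 19 features raised by the JIP1 hairpin could reflect a larger share of fibroblasts, since Ctgf and Cyr61 are abundant in them. The fibroblast and matrix list, however, had a median change of 0.05 (bootstrap 95% limits -0.213 to 0.194 over 31 features). From the spread between libraries its difference was -0.048 (95% limits -1.058 to 0.963), below the smallest rise among the 19, 1.73. This argues against a larger share of fibroblasts as the sole cause of these rises. The 19 were selected by passing the threshold, which favours large rises. The limits also reach 0.963, so a smaller contribution stays open. Within the list, 19 features were higher and 12 lower. Its most abundant gene, Sparc, was at 774 and 755.5 FPKM in PE+TSA and 733.2 and 593.3 with the hairpin (log2 change -0.213). Of the next most abundant, Fn1, Col1a1 and Bgn (listing 2 of 2) changed by 0.264, 0.15 and 0.196. Vim and Ogn (listing 2 of 2) changed by -0.792 and -2.098, and none of these passed. Of the genes of this list 1, Gsn, is also in another list. Under the 2 other scalings the lower of the 2 medians of the 19 was 2.376 against 2.614 as reported, and 18 or 19 of them still passed. The median of all features moved only from -0.003 to -0.013 and 0.03. These values argue against a scaling difference of the kind that such methods correct, although a shift common to most features could not be seen. A response to the hairpin itself or to the loss of JIP1 stays open as a hypothesis, and with 1 hairpin these were not separated. Whether Ctgf, Cyr61 and Amotl2 stand for YAP/TAZ target genes was tested on a list of 22 written from general knowledge, in which the 10 tested features that had not been seen or listed before had a median of 0.108, 6 of 10 higher (camera p = 0.704, 0.781 with an estimated correlation); the values decide neither way. The whole list had camera p = 7.17e-05 (0.0926 with an estimated correlation), and without Ctgf, Cyr61 and Amotl2 its 15 tested features had a median of 0.117 (camera p = 0.0863, 0.302 with an estimated correlation).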
